A study of Mus musculus with 6 samples.

How the data were processed

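Small RNA from exosomes of RAW 264.7 cells was compared between 3 control and 3 infected samples, each labelled 12 h. Per the labels' protocols, the cells were grown in DMEM with fetal bovine serum, exosomes were taken from culture medium with an Umibio isolation kit, RNA was extracted with a miRNeasy Serum/Plasma Advanced kit, and libraries were read on a NovaSeq instrument. The labels do not say whether the serum had been cleared of vesicles.

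The authors deposited 1 table of RPM values (reads scaled to a fixed total) for 1199 entries and 6 columns, whose name calls the unit TPM. In each column the deposited RPM values sum to 1000000 and are whole multiples of 1 step that is the same for every entry, so the unit is RPM with no length term. Per the submitters' processing notes, the genome build was GRCm39 and DESeq2 was used, with no version given. The aligner, the counter, the miRBase release and any filter are not given in the sources used here. Of the 391 unannotated loci, 202 have exactly the same values as another locus of the table, and near-identical miRNAs, such as the let-7 paralogs, miR-486a-5p and miR-486b-5p, or miR-199a-3p and miR-199b-3p, can share reads, so single members of such groups are uncertain, and so are shares summed over them. No sequence or position accompanies the entries.

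Whole reads were recovered by dividing each column by its step, and 100% of the 3549 values above 0 came out whole within 0.1 of a read. The sums, 42542 to 1853367 reads, are the reads assigned to entries of the table and not the sequenced totals. Reads were not marked with molecular identifiers as far as the sources used here say, so intervals (95%, exact Clopper-Pearson) and the limit of 3 reads behind a value of 0 cover counting error only.

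Because the name of the deposited table calls the unit TPM, a count test was not planned as the main result. The main test was limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(RPM + 1), for the 689 entries with a mean of at least 10 RPM over the 6 samples, with no covariate. Tests were two-sided with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPM + 1) scale and are infected minus control. The added 1 shrinks the change of entries near 1 RPM, and where a library with few reads holds 0 it can enlarge the change, as for miR-5126 (3.41, against 1.44 with edgeR, 1.72 with DESeq2 and 2.29 with a pseudocount of 10). The moderation took the spread of each entry from the fitted trend alone, since the prior degrees of freedom were infinite. Design, lists and the alternatives not marked as added were fixed before the data were examined, from a table expected to hold normalized values. As alternatives, edgeR 4.0.16 (quasi-likelihood, TMM), DESeq2 1.42.0 and, added later, voom with quality weights were run on the recovered whole reads. Other alternatives were pseudocounts of 0.1 and 10, other filters on the mean, median-of-ratios and quantile scaling, robust moderation, sample weights, the replicate number as a block, and leaving out each sample. Added after the data were seen were leaving out control 1 and infected 1, log10 reads or a class of depth (under or over 150000 reads) as a term, miRBase-named entries only, the expected number of entries at equal reads, and reads thinned to 42542 in 20 seeded draws.

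Text names the 5 entries with the smallest p in each direction, because fewer than 5 passed with no overlap between the groups, then the 10 miRNAs with the highest mean, and members of 19 preset lists. miR-326-5p, the arms noted for infected 1 and the entries that separate libraries by reads were picked after their values were seen. The lists were Toll-like receptor induced miRNAs, the let-7, miR-15/16, miR-29, miR-30, miR-181 and miR-34 and miR-449 families, the miR-17~92 and paralogous, miR-232724, miR-10, miR-99, miR-100 and miR-125, Dlk1-Dio3 and Sfmbt2 clusters, myeloid, erythroid and serum, epithelial, stromal and endothelial, muscle and neuronal, and lymphocyte miRNAs, and entries that resemble rRNA or tRNA. The 16 lists with at least 3 tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. Camera without a library used the entries with a mean of at least 10 RPM over the rest, while medians given without a library are over the members and entries tested with all 6. Arm ratios were tested with limma on log2((5p + 1)/(3p + 1)) for 96 hairpins whose arms both had a mean of at least 10 RPM. Single values were compared by exact permutation of the 6 samples.

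The tests were checked on simulated reads with the libraries' sizes. With the dispersion edgeR gave each of the 689 entries (common value 2.38), limma called 6.14% and edgeR 36.1% of 64-fold changes, 1.34% and 11.5% of 16-fold changes and 0.150% and 1.12% of 4-fold changes among 689 entries, and 0% and 0.266% of unchanged entries. With every library at 1853367 reads the limma and edgeR values were 19.4% and 35.6% for 64-fold and 6.54% and 12.9% for 16-fold changes. With a dispersion of 0.1 at the real sizes, limma called 99.0% of 16-fold changes in entries with a mean of at least 100 RPM. For arm ratios, 64-fold changes were called in 1.36% of hairpins at the median of these dispersions (3.18) and 94.9% at a dispersion of 0.1 (unchanged hairpins, 0.0699% and 3.18%), and a 4-fold change of the let-7 list in 35% and 100% of draws. Hairpin sequences for base composition, split at the midpoint into a 5p and a 3p side, came from the transcripts of a reference annotation on build GRCm38, which differs from the submitters' build, so no coordinates are given.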

Results

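Exosomes are small membrane vesicles that cells release, and their small RNA was sequenced here after isolation from the medium of RAW 264.7 cells, a mouse macrophage line. The control group (n = 3) was cultured normally, and the infected group (n = 3) received Salmonella, an intracellular bacterial pathogen, at 20 bacteria per cell. All 6 samples are labelled 12 h. The comparison of the groups asks whether the miRNA content of exosomes from these macrophages differs after infection. The labels do not say whether the samples of a group came from separate cultures, so the spread between these samples may be technical. In the main limma fit this spread was pooled over entries of like level and not taken from each entry alone. Camera compares the members of a list with the other entries. Neither kind of p-value therefore measures the spread of an entry between separate cultures.

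The values are RPM, reads scaled so that each library totals 1000000, for 1199 entries, 808 of them miRNAs with miRBase names and 391 unannotated loci that carry only a number. Control 1, 2 and 3 held 42542, 122553 and 1853367 reads, and infected 1, 2 and 3 held 59720, 306984 and 373495 reads, a 43.6-fold range. One read was worth 23.5 RPM in control 1 and 0.540 RPM in control 3, so a value of 0 allows up to 70.5 RPM in control 1 and up to 1.62 RPM in control 3 (3 reads each, counting error only). Unannotated loci took 14.5% of the reads of infected 1 (95% Clopper-Pearson interval 14.2% to 14.8%), against 0.201% to 2.53% in the 3 control libraries and 1.18% and 1.88% in infected 2 and infected 3. Over the miRBase-named miRNAs that were tested, infected 1 correlated with the other 5 libraries at Spearman rho 0.621 to 0.745, while infected 2 and control 3 correlated at 0.938 (across entries, which are not independent replicates).

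**Figure D1:**
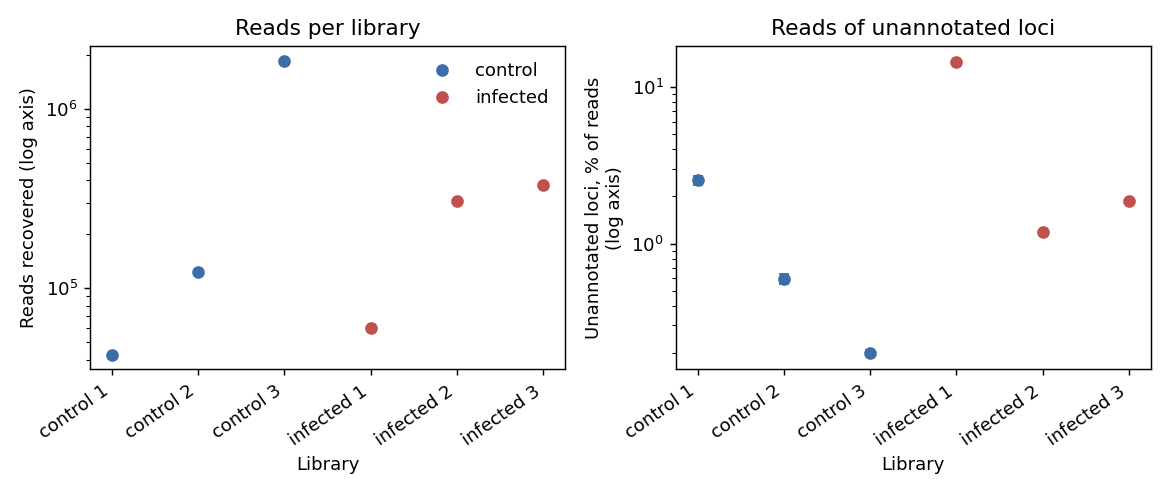
Reads recovered per library (left, log axis) and percent of reads of unannotated loci (right, log axis, bars are 95% Clopper-Pearson intervals) for the 3 control (blue) and 3 infected (red) libraries. Reads run from 42542 to 1853367, and infected 1 lies at 14.5% unannotated reads while the other 5 libraries lie between 0.201% and 2.53%.

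The exosome libraries of both groups were led by let-7 family members and by products of the miR-17~92 cluster and its paralogs. let-7c-5p stood at 119066 ± 99684 RPM in control and 130976 ± 59537 RPM in infected exosomes (SD, n = 3 each), and let-7b-5p at 54982 ± 33869 and 66645 ± 16770 RPM. miR-92a-3p stood at 83539 ± 35137 and 117170 ± 53790 RPM, miR-25-3p at 100744 ± 32235 and 91795 ± 14820 RPM, miR-19b-3p at 69158 ± 65864 and 23190 ± 11668 RPM, and miR-17-5p at 28484 ± 13178 and 19854 ± 787 RPM. miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, stood at 49302.5 ± 6822 RPM in control and 29431.5 ± 16646 RPM in infected exosomes, and every infected library lay below every control library. Infected 1 held 10365 RPM of it, against 36855 and 41074 RPM in infected 2 and infected 3. The log2 change of miR-146a-5p was -0.97, and it was -0.33 without infected 1, -0.51 with edgeR and 0.23 with voom. miR-23a-3p, let-7d-3p and miR-191-5p complete the 10 most abundant miRNAs, with control means of 51156, 31428.5 and 27984 RPM and infected means of 30216, 32160 and 25005 RPM. None of these 10 passed the test: their log2 changes, infected minus control, lay between -1.02 (miR-19b-3p, SE 0.67, and -0.18 without control 1) and 0.45 (miR-92a-3p, SE 0.67), with limma adjusted p from 0.793 to 0.988. With median-of-ratios scaling the values of miR-25-3p, let-7d-3p and miR-191-5p changed sign. Without control 1 the log2 change of let-7c-5p turned from 0.40 to -0.20 and that of let-7b-5p from 0.44 to -0.01.

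Of 689 entries with a mean of at least 10 RPM (370 named miRNAs and 319 unannotated loci), 1 was higher and 0 were lower in infected exosomes at a limma adjusted p under 0.05. The 1 entry that passed was the unannotated locus 18_13990, for which the table gives neither sequence nor position. Its mean was 671 ± 650 RPM in control and 9171 ± 7977 RPM in infected exosomes (SD, n = 3 each), a log2 change of 3.38 (SE 0.74, adjusted p = 0.00335). Single libraries held 235, 359 and 1418 RPM in the control group and 820, 9981 and 16712 RPM in the infected group, so infected 1 lay below control 3. Infected exceeded control 2.76-fold among the 3 libraries under 150000 reads and 9.41-fold among the 3 over it (ratios of means, from 1 or 2 libraries of each group). The SE of 0.74 came from the spread of entries of like level, while the spread of 18_13990 alone gave an SE of 1.55 and an exact permutation p of 0.2 (two-sided, on the log2 values). The median log2 change of all 689 entries was 0.77, with -0.11 over the named miRNAs and 2.22 over the unannotated loci, and it was -0.03 without infected 1. Median-of-ratios scaling moved the log2 changes by a median of 0.17 and quantile normalization by -0.83. At an unadjusted p under 0.05, limma had 7 entries higher and 5 lower. On the whole reads behind the RPM values, edgeR and DESeq2 called 0 entries (unadjusted, 51 higher and 1 lower with edgeR, 34 and 7 with DESeq2), and voom called 18_13990 alone (unadjusted, 25 and 26). With quantile normalization limma called 0 entries (unadjusted, 1 and 4).

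The call of 18_13990 ended when control 1, control 2, infected 2 or infected 3 was left out (0 entries higher without control 1, control 2 or infected 3, and 2, miR-23a-5p and miR-326-5p, without infected 2), and with edgeR (adjusted p = 0.421), against a range of 6.13e-09 to 0.979 over all alternatives run. The log2 change stayed positive in these fits, at 2.85, 3.16, 2.91 and 2.54 without these libraries in turn and 3.72 with edgeR. With the class of libraries under or over 150000 reads as a term in the model, 18_13990 had a log2 change of 2.34 (SE 0.68, adjusted p = 0.0658), while miR-23a-5p, miR-326-5p and a pair of unannotated loci with identical values were called higher and miR-582-5p lower. Infected 1 is the only infected library under 150000 reads. Without it the log2 changes of miR-23a-5p, miR-326-5p and miR-582-5p were -0.49, -0.86 and -1.64.

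No named miRNA passed in either direction, and the 4 with the smallest p among those with higher values after infection were miR-23a-5p, miR-5126, miR-139-3p and miR-25-5p. miR-23a-5p, the minor arm of its hairpin, had a log2 change of 2.57 (SE 0.88, limma adjusted p = 0.793), but its 69173 RPM in infected 1 stood against 35.8 and 383 RPM in infected 2 and infected 3 and 306, 384 and 38.3 RPM in the control libraries. Without infected 1 its log2 change was -0.49. miR-139-3p (log2 change 3.33, SE 1.37) and miR-25-5p (3.14, SE 1.44) also had their highest values, 1088 and 3550 RPM, in infected 1. miR-5126 stood at 91.7 ± 85.4 RPM in control and 311 ± 154 RPM in infected exosomes (log2 change 3.41, SE 1.24, adjusted p = 0.793). It is listed at 0 in control 1, where that value allows 70.5 RPM, and its log2 change was 1.05 without control 1 and 1.44 with edgeR. miR-139-3p and miR-25-5p are also listed at 0 there, and without control 1 their changes were 1.20 and 1.07.

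The 5 miRNAs with the smallest p among those with lower values were miR-301a-3p, miR-142a-5p, miR-582-5p, miR-223-3p and miR-19a-3p. miR-142a-5p and miR-223-3p are abundant miRNAs of myeloid cells. miR-142a-5p stood at 10706 ± 7087 RPM in control and 2621 ± 1156 RPM in infected exosomes (log2 change -1.77, SE 0.69), and miR-223-3p at 821 ± 926 and 124 ± 88.0 RPM (-2.22, SE 1.01; SD, n = 3 each). The change of miR-223-3p was -1.15 without control 1, -3.46 without control 3 and -1.26 without infected 2. miR-582-5p stood at 237 ± 193 and 39.0 ± 33.9 RPM (-3.60, SE 1.43) with no overlap between the groups. It is listed at 0 in infected 1, where that value allows 50.2 RPM, and the log2 change was -1.64 without infected 1 and -2.51 with edgeR. miR-301a-3p had a log2 change of -2.12 (SE 0.80) and miR-19a-3p of -1.43 (SE 0.67). All 5 had a limma adjusted p of 0.793, and by the same test all but miR-582-5p were higher in the libraries under 150000 reads than in those over it. Without control 3, miR-301a-3p and miR-19a-3p passed, with log2 changes of -3.29 and -2.72, while without control 1, which held 9261 and 62315 RPM of them, the changes were -0.86 and -0.33 (adjusted p = 0.979 and 0.984). Over all 689 entries, 33 (4.79%) had no overlap between the groups, against 10% by chance with 3 samples in each for values without ties. Entries at 0 in most libraries, such as the 126 unannotated loci found only in infected 1, cannot be without overlap. Where such entries were tested they put the chance share below 10%.

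**Figure D2:**
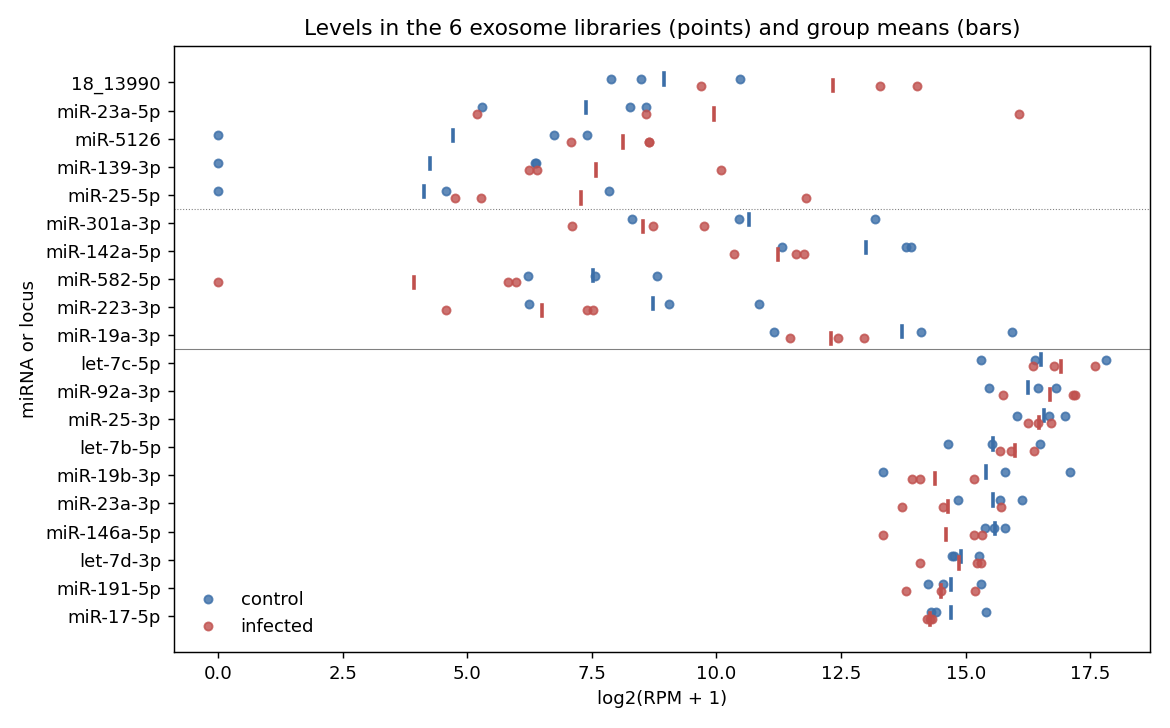
Level, as log2(RPM + 1), of the 5 entries with the smallest p in each direction (upper 2 blocks) and of the 10 most abundant miRNAs (lower block). Points are the 3 control (blue) and 3 infected (red) libraries and bars are group means; 18_13990 alone passed the test, and the infected mean of miR-23a-5p rests on 69173 RPM in infected 1.

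MiRNAs that macrophages raise after Toll-like receptor stimulation showed no common direction. Of 18 measured members of that list, 8 had higher and 10 lower values after infection, and 0 passed over all entries or adjusted over the list alone. miR-155-5p, a promoter of inflammatory signalling, stood at 749 ± 456 RPM in control and 764 ± 503 RPM in infected exosomes (log2 change -0.13, SE 0.82, SD, n = 3 each). miR-146b-5p stood at 9282 ± 3825 and 12580 ± 10135 RPM (0.03, SE 0.67), miR-21a-5p at 19113 ± 9435 and 20265 ± 18182 RPM (-0.21, SE 0.67) and miR-132-3p at 56.6 ± 60.8 and 122 ± 68.2 RPM (2.57, SE 1.52, and 0.47 without control 1, where it is listed at 0). The log2 changes of miR-155-5p and miR-146b-5p were 0.70 and 0.93 without infected 1, and -0.53 and -0.64 without infected 3. The median of the list was -0.13 and its mean 0.11, the camera direction was down (limma adjusted p = 0.497), and fry, which asks whether the members move one way on balance, had the direction up (adjusted p = 0.963). The median turned to 0.16 with median-of-ratios scaling, and without infected 1 camera placed the list up (adjusted p = 0.0369) while without control 1 or infected 3 it placed it down (adjusted p = 0.0243 and 0.0254), as it did with the depth class as a term (adjusted p = 0.0118).

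The 12 myeloid entries of the table included 10 that were tested, and 8 of these had lower and 2 higher values after infection. miR-142a-3p, from the same hairpin as miR-142a-5p, stood at 2325 ± 2423 RPM in control and 646 ± 510 RPM in infected exosomes. The list was lower relative to the other entries by camera with a preset correlation of 0.01 (median log2 change -0.86, adjusted p = 0.000817). It did not pass with an estimated correlation (adjusted p = 0.256) or without infected 1 (adjusted p = 0.619), where the median of its 10 members stayed at -0.86 while that of the 689 entries went from 0.77 to -0.03. Over the entries that camera tested without infected 1, the median of the list was -1.38 and that of all entries -0.50. Without control 1 its median was -0.30 and it passed (adjusted p = 0.00662). miR-155-5p, miR-146a-5p and miR-21a-5p belong to this list and to that of Toll-like receptor induced miRNAs. Myeloid miRNAs took 2.05% of the reads of infected 1 (95% Clopper-Pearson interval 1.94% to 2.17%) and 6.25% to 9.62% of those of the other 5 libraries.

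miR-17~92 and its paralogous clusters, which promote proliferation, had 10 of 11 tested members with lower values after infection (median log2 change -0.43), and the list was lower by camera (adjusted p = 0.00205, and adjusted p = 0.506 with an estimated correlation). miR-20b-5p had a log2 change of -2.30 (SE 1.72) and miR-18a-5p of -1.01 (SE 0.91), which were -1.12 and -0.47 without control 1, while miR-92a-3p, at 0.45, was the member with a higher value (0.07 without control 1). The list did not pass without infected 1 (camera adjusted p = 0.440) or without control 1 (adjusted p = 0.0592, its median then -0.18). Without infected 1 its median was -0.46. That of all entries was then -0.50 over those that camera tested in that fit, and -0.03 over the 689 entries.

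Of the 5 lists of miRNAs of other cell types, set as markers of RNA that does not come from macrophages, 3 were lower, and so was the Dlk1-Dio3 cluster. The epithelial and lymphocyte lists did not pass. Stromal and endothelial miRNAs had 9 of 9 tested members with lower values (median log2 change -1.77, camera adjusted p = 7.64e-06, and adjusted p = 0.256 with an estimated correlation). Among them, miR-126a-3p stood at 238 ± 190 RPM in control and 20.7 ± 12.0 RPM in infected exosomes (-2.77, SE 1.45). The change of miR-126a-3p was -4.17 without control 3, -2.07 without control 1 and -1.87 with the depth class as a term. Its infected mean lies below the 50.2 RPM that a value of 0 allows in infected 1. miR-199a-5p stood at 446 ± 246 and 102 ± 16.4 RPM (-1.93, SE 1.01). Erythroid and serum miRNAs had 8 of 8 lower (median -1.56, adjusted p = 0.000817, and adjusted p = 0.506 with an estimated correlation), with liver-derived miR-122-5p at 1536 ± 1217 and 2564 ± 3885 RPM (-0.04, SE 0.79, and -1.54 without infected 1 but 0.92 without infected 3). Muscle and neuronal miRNAs had 4 of 4 lower (median -3.04, adjusted p = 0.00603, and adjusted p = 0.394 with an estimated correlation), including miR-138-5p at 66.2 ± 50.9 and 5.04 ± 4.89 RPM. Of the 7 tested members of the Dlk1-Dio3 cluster, an imprinted locus, 6 were lower (median -1.70, adjusted p = 0.0315, and adjusted p = 0.712 with an estimated correlation). Among these, miR-369-3p stood at 280 ± 356 and 144 ± 238 RPM. The muscle and neuronal list held only 19, 40 and 62 reads in control 1, 2 and 3 and 11, 5 and 9 in infected 1, 2 and 3. The Dlk1-Dio3 list held 54, 46 and 14 reads in control and 44, 7 and 2 in infected libraries. With so few reads the size of both medians can depend on the added 1 RPM, though camera also passed both lists with a pseudocount of 10 (adjusted p = 0.00494 and 0.0440). The Dlk1-Dio3 list did not pass without control 1, control 2, infected 1, infected 2 or infected 3 (adjusted p 0.0503 to 0.313). Its median in these fits was -0.19, -1.34, -3.42, -0.60 and -0.52, so it was smaller in size without control 1, control 2, infected 2 or infected 3 but not without infected 1. Muscle and neuronal miRNAs did not pass without control 2 or infected 1 (adjusted p = 0.0912 and 0.0750), with medians of -3.32 and -2.54. Erythroid and serum miRNAs took 0.484%, 0.368% and 0.0512% of the reads of control 1, 2 and 3 and 0.759%, 0.0795% and 0.0415% of those of infected 1, 2 and 3 (Spearman rho of share and reads -0.886, exact p = 0.0333, adjusted p = 0.0667 over 6 lists). The rho was -0.543 for stromal and endothelial miRNAs, with 0.201% in control 2 and 0.193% in control 3, -0.714 for muscle and neuronal miRNAs and -0.943 for the Dlk1-Dio3 cluster (exact p = 0.297, 0.136 and 0.0167, adjusted p = 0.297, 0.163 and 0.05). Leaving out 1 library moved these medians. Without control 1 that of stromal and endothelial miRNAs was -0.79, that of erythroid and serum miRNAs -0.71 and that of muscle and neuronal miRNAs -1.80. Without control 3 they were -2.49, -2.55 and -3.90. Without infected 3 the stromal and endothelial median was -1.10. In total 6 of 16 lists passed, all lower, against 3 of 16 when only miRBase-named entries were tested (stromal and endothelial, erythroid and serum, and muscle and neuronal miRNAs), and 0 with an estimated correlation or with fry. With log10 reads as a term the same 6 lists passed, all lower, and with the depth class 4 of these 6 did, without erythroid and serum miRNAs (adjusted p = 0.0545) and the Dlk1-Dio3 cluster (adjusted p = 0.360). Mean log10 reads were 5.33 in control and 5.28 in infected libraries. A linear term could therefore move the changes little, and other forms of depth are not covered by it. Without control 1 and infected 1, the libraries with the fewest reads, 2 lists passed, of which stromal and endothelial miRNAs were lower and the miR-15/16 family was higher.

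**Figure D3:**
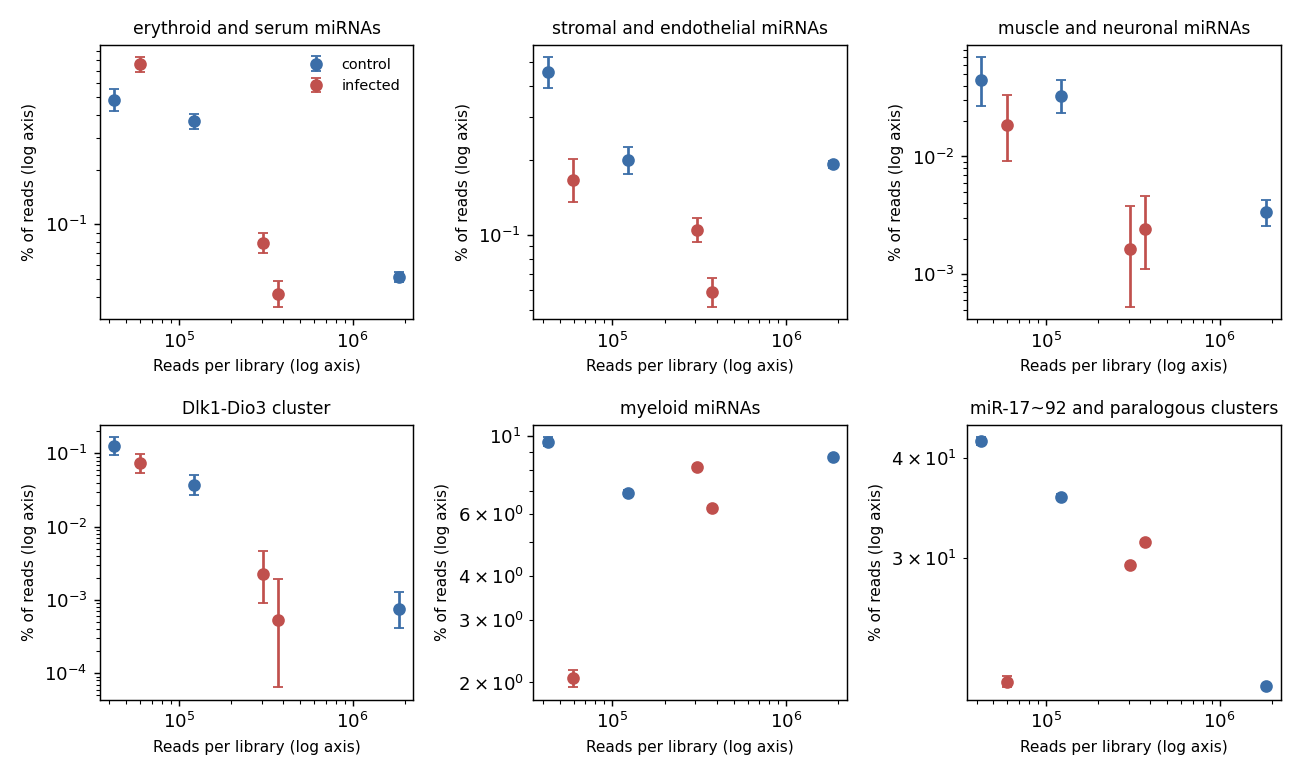
Percent of a library's reads taken by each of the 6 lists that passed (log axis) against its number of reads (log axis), for the 3 control (blue) and 3 infected (red) libraries, with 95% Clopper-Pearson intervals. The erythroid and serum share runs from 0.759% in infected 1 to 0.0415% in infected 3, and the myeloid share is 2.05% in infected 1.

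The other lists did not pass with all 6 libraries. The let-7 family had 7 of 11 members with higher values (median log2 change 0.42, camera adjusted p = 0.894), the miR-15/16 family 5 of 6 (0.58, adjusted p = 0.536) and the clusters of miR-10, miR-99, miR-100 and miR-125 6 of 7 (0.41, adjusted p = 0.536). The miR-232724 clusters had 5 of 10 (median 0.04, and -0.06 with quantile normalization, adjusted p = 0.888), with 1 member, miR-23a-5p, passing adjusted over the list alone. The miR-29 family had 1 of 3 members with a higher value (-0.75, adjusted p = 0.389), and the miR-30 family 1 of 4 (-0.09, and 0.21 with median-of-ratios scaling, adjusted p = 0.536). Epithelial miRNAs had 1 of 5 higher (-0.43, adjusted p = 0.279) and were led by miR-183-5p at 5084 ± 2656 RPM in control and 4733 ± 2544 RPM in infected exosomes. Lymphocyte miRNAs had 2 of 3 higher, miR-181a-5p and miR-181b-5p, and miR-150-5p lower (median 0.50, mean -0.34, camera down, adjusted p = 0.536). The entries that resemble fragments of rRNA or tRNA had 3 of 4 higher (median 0.01, mean 0.09, camera down, adjusted p = 0.682). The miR-181 and miR-34 and miR-449 families had 2 tested members each, too few for the test, with medians of 0.60 and -0.87 (0.20 without control 1 for the latter). With the filter at a mean of 1 RPM both were tested, and the miR-34 and miR-449 family passed as lower (adjusted p = 0.0444). The Sfmbt2 cluster had 0 entries in the table. Leaving out 1 library turned the sign of several of these medians. Without control 1 it was 0.09 for the miR-29 family, 0.29 for the miR-30 family and -0.10 for the clusters of miR-10, miR-99, miR-100 and miR-125. Without infected 1 it was 0.21 for the miR-30 family, -0.27 for the miR-232724 clusters and -0.33 for the entries that resemble rRNA or tRNA. Without control 2 it was -0.49 for lymphocyte miRNAs, and 0.02 for the let-7 family, close to 0. The median of the miR-15/16 family kept its sign but was 0.10 without infected 3 and 0.99 without infected 1. That of the miR-181 family was 0.06 without control 2 and 1.42 without control 1. Leaving out 1 library also made some of the lists pass. The let-7 family was higher without control 3 (camera adjusted p = 0.0309), the miR-15/16 family and the clusters of miR-10, miR-99, miR-100 and miR-125 were higher without infected 1 (0.0200 and 0.0149), and epithelial miRNAs were lower without control 1 (0.0117). Apart from miR-23a-5p, no list had a member that passed adjusted over the list alone.

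The log2 ratio of the 5p to the 3p arm, with 1 RPM added to each arm, passed for 0 of 96 hairpins with limma. The added 1 RPM sets the ratio where an arm holds 0 reads: for miR-25 it was -16.67 in control 1, where miR-25-5p is listed at 0, and -11.69 to -4.47 in the other 5 libraries. The smallest p belonged to miR-29a, whose log2 5p to 3p ratio was -4.77, -4.91 and -5.77 in control and -6.29, -6.70 and -7.76 in infected exosomes (change -1.77, SE 0.79, limma adjusted p = 0.845). For miR-15b the ratio was -2.67, -3.10 and -3.26 in control and -1.82, -1.72 and -1.71 in infected exosomes (change 1.26, SE 0.62, adjusted p = 0.845). For miR-23a the ratio was 0.37 in infected 1 and between -9.56 and -5.13 in the other 5 libraries. Without control 1 and infected 1 the count was again 0.

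The breadth of the libraries did not separate the groups. Control libraries held 566 ± 190 and infected libraries 617 ± 107 detected entries (SD, n = 3 each, two-sided exact permutation p = 0.7), a difference of 51.7 that was -29.7 without control 1 and -6.17 without infected 1. Counted at 42542 reads the expected numbers were 367 ± 63.8 and 445 ± 218 (exact permutation p = 0.8). In miRBase-named miRNAs alone the numbers were 457 ± 175 and 439 ± 24.2, a difference of -18.3 (exact permutation p = 1). The 10 most abundant entries of each library took 63.9% ± 4.24 of the reads in control and 62.0% ± 9.68 in infected exosomes (exact permutation p = 0.8), a difference of -1.96 percentage points that was 3.29 without infected 1. With 3 samples in each group the smallest p this test can give is 0.1.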

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

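Voom, the terms for reads or depth class, miRBase-named entries only, leaving out control 1 and infected 1 together, thinned reads and the expected number of entries at equal reads were chosen after seeing the data, the other tests before. The number of entries higher after infection, 1, was 0 with a pseudocount of 10, a mean of at least 100 RPM, quantile normalization, edgeR, DESeq2, miRBase-named entries only, thinned reads, or without control 1 and infected 1, and 4 with the depth class as a term. With the pseudocount of 10, the mean of at least 100 RPM and quantile normalization, the change of 18_13990 stayed at 3.36, 3.38 and 3.26, and its SE grew from 0.74 to 0.92, 1.08 and 1.39 because limma gave its own spread more weight (prior degrees of freedom infinite, then 18.8, 6.38 and 5.41). The number lower, 0, was 1 with the depth class. Leaving out single samples gave 0 to 2 higher and 0 to 2 lower, 4 to 7 lists and 0 hairpins. The 6 lists became 0 with an estimated correlation and 0 with fry, 2 without control 1 and infected 1, 3 with miRBase-named entries only, 7 with a mean of at least 1 RPM (the miR-34 and miR-449 family added), and 5 with the depth class (4 of the 6, and Toll-like receptor induced miRNAs), while with log10 reads the same 6 passed. The groups had nearly equal mean log10 reads, so that term could move the changes little. The difference in detected entries, 51.7, ran from -29.7 to 156 when single samples were left out, and was -18.3 for miRBase-named miRNAs and -87.5 without control 1 and infected 1. The difference in the share of the 10 most abundant entries, -1.96 percentage points, ran from -6.25 to 3.29 when single samples were left out and was 0.872 without control 1 and infected 1. With miRBase-named entries only, all 319 tested unannotated loci drop out of the comparison by construction. The median log2 change of the entries compared is then -0.11 and not 0.77. That is nearer to the medians of the lists lost: miR-17~92 and paralogous clusters (-0.43), myeloid miRNAs (-0.86) and the Dlk1-Dio3 cluster (-1.70). Any other cause of the loss was not tested.

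Deviations of samples with the same number correlated at -0.09, -0.20 and 0.15, and only control 3 and infected 3 correlated best with each other. With 3 samples in each group these correlations cannot exclude a pairing, which the labels do not state. With a replicate block, 1 entry was higher, 0 lower, 6 lists and 0 hairpins passed, so the block changed no count. For the 81 entries examined singly, 1704 of 1917 values kept direction and side of the threshold, 194 changed sign without passing in either fit, 12 lost a call, all of 18_13990, and 7 gained one. Depth sets what a value of 0 can exclude, up to 70.5 RPM in control 1. In simulations with the spread of these libraries, limma called 6.14% of 64-fold changes at the real sizes and 19.4% with every library at the size of the largest, and edgeR 36.1% and 35.6%.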

Other observations

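The tests of the 3 patterns below were chosen after the values were seen, and the counts over other splits of the samples before. In exosomes of both groups 55 of 96 hairpins had the same arm in excess throughout: 31 had more 5p and 24 more 3p reads in all 6 libraries. In 11 hairpins, among them miR-23a, miR-27a, miR-139, miR-125a and miR-351, infected 1 alone had the other arm in excess, against 1 to 3 hairpins for each of the other 5 libraries. Control 3, infected 2 and infected 3, the libraries over 150000 reads, were the most alike in miRBase-named miRNAs (Spearman rho 0.920 to 0.938 across entries, which are not independent replicates), above control 1 and control 2 (0.784). Control 2, though under 150000 reads, was nearer to these larger libraries (0.851 to 0.862) than to control 1.

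With control 1, control 2 and infected 1 on one side, 39 entries were higher in the libraries under 150000 reads and 1, 18_13990, was higher in those over it (limma). Of the 39, 27 are miRBase-named and 7 of these belong to the lists of other cell types or the Dlk1-Dio3 cluster. Among the 39 were miR-122-5p of liver (log2 difference, over minus under, -3.75, SE 0.66, adjusted p = 6.51e-05), miR-150-5p of lymphocytes (-4.50, SE 1.18), miR-145a-5p of smooth muscle (-5.43, SE 1.45), and the myeloid miR-142a-5p (-2.06, SE 0.59) and miR-223-3p (-2.99, SE 0.89). These samples were grouped by reads, not by the study.

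Infected 1 was richer than the other 5 libraries in unannotated loci and in arms that are otherwise rare. Of 391 unannotated loci, 284 were at least 4 times higher in infected 1 than in any other library, as were 25 of 160 miRNA arms with at least 10 reads there, such as miR-23a-5p (69173 RPM), miR-326-5p (12609 RPM), miR-365-2-5p (4622 RPM) and miR-92a-1-5p (1273 RPM). Of the 18 raised arms with both arms in the table, 16 are the minor arm. The counts of loci and arms are not like measures. The 391 are all unannotated loci, 202 of them with the same values as another, so the same reads can count more than once. A value of 0 in control 1 also allows up to 70.5 RPM, so the excess of loci with few reads is uncertain. The tables argue against a low read number, since control 1, with fewer reads, had 0.175 times the unannotated share, and against infection as the whole cause, since infected 2 had 1.18% and infected 3 1.88%, below the 2.53% of control 1. The sides of the hairpins that carry the raised arms held more G, 37.4% ± 9.49 (SD, n = 25) against 26.7% ± 7.58 (n = 135), by 10.7 percentage points (95% bootstrap interval 6.78 to 14.6, permutation p = 1e-05, the smallest these permutations can give). The other arms were not matched for minor or major arm, so a difference in G cannot be told apart from one of arm type. Arms of 1 library, some of them paralogs such as miR-23a-5p and miR-23b-5p, are also not independent replicates. A preparation or base-calling step that favours G-rich sequence is therefore only a candidate explanation. Fragments of other RNAs or a difference in the cells behind this 1 library stay open and were not tested.

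The share of erythroid and serum miRNAs tended to be lower in libraries with more reads (Spearman rho -0.886, exact p = 0.0333, adjusted p = 0.0667 over 6 lists; Pearson r of log2 share and log10 reads -0.879, exact p = 0.0278, adjusted p = 0.0556; r -0.987 without control 1 and control 3). Infection as the whole cause is argued against, because the share was 9.47 times (control) and 18.3 times (infected) higher in the library with the fewest reads than in that with the most within each group. A fixed amount of outside RNA diluted in the larger libraries, which could come from the serum of the medium, stays open, because the rho of -0.886 does not pass when adjusted. Lymphocyte and Dlk1-Dio3 shares had rho -0.943 each (exact p = 0.0167, adjusted p = 0.05), stromal and endothelial -0.543 (exact p = 0.297), muscle and neuronal -0.714 (exact p = 0.136), while the epithelial share went the other way (0.771, exact p = 0.103).

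The locus 18_13990 was higher after infection and higher in the libraries over 150000 reads (log2 difference, over minus under, 3.91, SE 0.67, limma adjusted p = 4.61e-05). A linear trend with log10 reads did not take up the change. Mean log10 reads were 5.33 in control and 5.28 in infected libraries, and with the trend in the model the change was 3.50 (SE 0.62, adjusted p = 1.45e-05). That SE was moderated toward the spread of other entries, while the spread of the locus alone gave an SE of 0.97 and an interval of 0.42 to 6.58. This interval is unadjusted for a locus picked among 689. So only the size of the change argues against a linear trend as the whole cause, and other forms of depth are not covered. With the depth class the call ended because the change shrank from 3.38 (SE 0.74) to 2.34 (SE 0.68, adjusted p = 0.0658; own interval 0.45 to 4.23). Infected exceeded control in both classes, 2.76-fold under and 9.41-fold over 150000 reads, but depth class as the whole cause stays open, because the change misses the adjusted threshold and the own interval is unadjusted for a locus picked among 689. The call without these terms also rests on the spread of other entries: the spread of the locus alone gives an SE of 1.55 and an interval from -0.93 to 7.70, and edgeR gave an adjusted p of 0.421.

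The 6 samples split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For entries higher after infection (1), 5 of the 10 splits, the real one included, gave as many calls in one direction, with 39 as the highest of the other splits. That highest split is the one by reads, control 1, control 2 and infected 1 against the rest. It cannot separate depth from what sets infected 1 apart, since miR-23a-5p, miR-326-5p and miR-365-2-5p, raised in infected 1, are among the 39. With the depth class in the model 4 entries were higher and 1 lower after infection, counting both loci of a pair with identical values. Infected 1 is the only infected library under 150000 reads. Without it the log2 changes of miR-23a-5p and miR-326-5p were -0.49 and -0.86. For the 6 lists, 5 of 10 splits gave as many, with 9 as the highest other. That was control 1, control 2 and infected 2 against the rest, while the split by reads gave 5 lists. For entries lower (0) and hairpins (0) all 10 of 10 splits reach the count by construction, so the comparison says nothing there (highest other 39 and 0).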
